A study of Mus musculus with 45 samples.

How the data were processed

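Messenger RNA was sequenced from 45 cultures of mouse forelimb buds. The buds came from CD1 embryos of gestation day 13 and spent 3, 24 or 48 h in culture with 1 µM bisphenol AF (BPAF), with 5 µM BPAF, or with the solvent DMSO as control. Per the labels' protocols, limbs of both sexes were pooled in culture bottles and RNA was selected for poly-A. Each dose and time makes a group of 5 libraries, which gives 9 groups. Each library was assigned to its group by its label. The treatment text of the labels spells the compound out once as bisphenol A, while titles and doses name BPAF, and BPAF is used here. One characteristic of 1 µM 3 h replicate 5 names another compound and dose (10 uM BPA), while its title and library code place it at 1 µM BPAF. It was kept there, and each result of that group was recomputed without it. The titles and the library codes of 1 µM 48 h replicates 1 and 2 carry each other's numbers. The labels do not say whether replicates were cultured on separate days, so p-values measure the spread between bottles or libraries, part of which may be technical.

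The deposited data are 9 tables, each comparing a pair of groups over 10 libraries. Per the file headers, the authors deposited raw read counts per gene for every library. The authors also deposited a normalized signal per library, which in each table equals the count divided by 1 size factor per library to within a relative deviation of 5e-10. Per the file headers, the authors gave FPKM values, which were proportional to count over gene length for 100.0% of genes within 1 percent. Per the file headers, each table also holds the authors' log2 fold change and the authors' p-value with its adjusted p-value. Per the submitters' processing notes, the tools were CASAVA 1.8, STAR 2.5, HTSeq 0.6.1 and DESeq2, with the genome build mm10. The notes used here give no role, filter or strand setting for them. A gene was listed in a deposited table only where its 10 libraries held at least 2 reads together, so an absent gene had at most 1 read there. Such absences made up 11.7% of gene and library combinations after joining and were read as 0 counts. Reads of near-identical gene copies, such as the alpha globins, the tubulins and the epidermal keratins, and of overlapping or antisense genes may be divided between genes in ways the sources used here do not describe.

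The raw counts were joined over tables into 35272 genes. Library totals lay between 14901842 and 25154115 reads, with a median of 17820524. Identifiers had a symbol in the name table used here for 35237 genes, which mattered because 24 symbols in the deposited tables had been turned into dates. Start and end positions in the deposited tables were the same as in GENCODE mouse release M21 for 97.7% of identifiers, and printed positions are those of the deposited tables, build mm10. The authors' fold changes and p-values were used only to count their calls. The normalized and FPKM values entered no test, because each table was scaled separately.

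Each comparison was fitted in edgeR 4.0.16 under R 4.3.3 with TMM scaling and the quasi-likelihood F-test on the libraries compared, without covariates. Low counts were filtered with filterByExpr at a minimum count of 10 and a minimum total of 15. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values of the first group over the second, given with their standard error (SE). Levels are TMM-scaled CPM, given as mean ± SD. Of the comparisons, 12 set a pair of groups against each other and 4 test whether a BPAF effect differs between adjacent times, with 20 libraries each. Gene lists for the cell types, signalling pathways and stress responses of the limb were fixed in number and membership (40 lists). Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at an inter-gene correlation of 0.01, with adjustment over the lists that had at least 3 measured members. Beside each list, the members called over all genes and the members called when adjusted over the list alone are counted. Camera was repeated with an estimated correlation, and fry was run as a test of whether a list moves to one side. A level of a list is the mean log2 CPM, in a library, of its members with a mean CPM of at least 2 over all 45 libraries. Group differences in that level were tested with a two-sided exact permutation test.

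Genes are named by a fixed rule. It takes 10 anchor genes of cartilage and bone (Sox9, Runx2, Runx3, Col2a1, Acan, Col10a1, Ihh, Sp7, Col1a1 and Mmp13), whatever their result. It adds the 8 called genes with the largest rise and the 8 with the largest fall at a mean CPM of at least 2, leaving out predicted, Riken, LOC and pseudogene symbols and genes with no symbol. Up to 4 called members of each list with the smallest p follow, and the 6 called genes with the smallest p in each test of a difference between effects. A gene named by the rule in any comparison may be given in another, and a list that did not move may have its top member given. Genes outside the rule are marked as chosen after their values were seen. The groups, comparisons, tests, lists, this rule and 8 of the alternative settings were chosen before the data were examined, and 2 settings were added afterwards.

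The alternatives were DESeq2 size factors in place of TMM, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom, a single model over all 45 libraries, the replicate number as a block, the mean log2 CPM of the Y-linked genes as a covariate, and leaving out each library in turn. The added settings leave out 7 libraries that hold tissue of 1 sex only, or 2 libraries of 24 h with over 0.2% of reads from haemoglobin genes. The 7 libraries had either a mean log2 CPM of Y-linked genes under 0 or an Xist level under 10 CPM.

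Whether replicate numbers pair libraries was checked from the correlation of same-numbered libraries' deviations from their group means over 12025 genes with a mean CPM of at least 5. Numbers were taken to pair libraries where each of the 5 correlations exceeded 0.1. With the numbers in the titles, this held for 1 µM against control at 24 h (0.134 to 0.437), for 5 µM against control at 24 h (0.15 to 0.578) and for 5 µM against 1 µM at 3 h (0.185 to 0.478). With the numbers in the library codes, it held for 1 µM against control at 48 h (0.173 to 0.477) and for 5 µM against 1 µM at 48 h (0.143 to 0.4). For 5 µM against control at 48 h 4 of the 5 correlations exceeded 0.1 and the lowest was 0.091, so the rule was narrowly missed. The pairing comes from the data, since the labels do not say what a number stands for. No pair of replicates came close to being a repeat of 1 library: the chi-square of their counts per degree of freedom was at least 4.63, against about 1 for sampling noise.

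The test was checked on counts simulated from the real libraries with 200 genes changed, 50 for each fold size. Shares of changed genes called are given as the range over 5 simulations, since each rests on 50 genes and moved between simulations. For 5 µM against control at 48 h, 16 to 36% of genes changed 1.25-fold were called, 62 to 70% at 1.5-fold, 78 to 84% at 2-fold and 92 to 96% at 4-fold. For 1 µM against control at 24 h these shares were 30 to 36%, 54 to 76%, 70 to 94% and 94 to 98%. For 5 µM against control at 24 h they were 14 to 24%, 56 to 70%, 72 to 88% and 92 to 96%. Of genes changed 1.5-fold, 58 to 72% were called for 1 µM against control at 3 h, 58 to 68% for 1 µM against control at 48 h and 56 to 70% for 5 µM against control at 3 h. For the differences in the 5 µM effect it was 24 to 48% between 3 and 24 h and 34 to 46% between 24 and 48 h. Other tests were run on 1 simulation for 5 µM against control at 48 h. There edgeR called 9 unchanged genes, limma-voom 6 and DESeq2 30, so calls made by DESeq2 alone carry less weight. In simulated lists of 30 genes for 5 µM against control at 48 h, camera called the list lowered 1.5-fold and 0 of 39 unchanged lists. The simulated genes varied independently of each other. This check therefore cannot show how often camera calls unchanged lists whose members vary together, as those of real lists may.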

Results

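Forelimb buds of gestation day 13 mouse embryos form cartilage, bone precursors, muscle and skin in culture, and the series followed their messenger RNA under bisphenol AF (BPAF), a fluorinated analog of the plastics chemical bisphenol A. Buds were cultured for 3, 24 or 48 h with DMSO as control or with 1 or 5 µM BPAF, and 5 libraries were sequenced per dose and time, 45 in all. Read totals per library lay between 14901842 and 25154115 reads (median 17820524). How small a change these depths could show was tested on simulated counts, as described with the processing. Time in culture separated the libraries far more than dose did, and the first principal component of log2 CPM held 56.41% of the variance over 12025 genes, against 7.17% for the second. Mitochondrial transcripts made up 1.57% ± 0.111 of reads in control libraries and 1.67% ± 0.0918 in 5 µM libraries at 48 h (SD, n = 5 each). Haemoglobin transcripts, from red blood cells, made up 0.271% ± 0.0436 of reads in control libraries at 3 h, 0.16% ± 0.052 at 24 h and 0.0685% ± 0.0148 at 48 h. With 5 µM BPAF these shares were 0.224% ± 0.0358, 0.154% ± 0.0589 and 0.054% ± 0.0084 (SD, n = 5 each).

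The genes followed most closely below are protein-coding, and their positions are given in build mm10. Pax7 (ENSMUSG00000028736), a transcription factor of muscle progenitors, lies on chromosome 4 from 139737062 to 139833528. Myh3 (ENSMUSG00000020908), the embryonic myosin heavy chain, lies on chromosome 11 from 67078300 to 67102291. Col10a1 (ENSMUSG00000039462), the collagen of hypertrophic cartilage, lies on chromosome 10 from 34389981 to 34397085, and Ibsp (ENSMUSG00000029306), bone sialoprotein, on chromosome 5 from 104299171 to 104311469. Mmp13 (ENSMUSG00000050578), a collagenase, lies on chromosome 9 from 7272514 to 7283331. Hspa5 (ENSMUSG00000026864), the main chaperone of the endoplasmic reticulum, lies on chromosome 2 from 34771970 to 34777547, and Trib3 (ENSMUSG00000032715), a pseudokinase induced by amino acid and reticulum stress, on chromosome 2 from 152337422 to 152344032. Abcg1 (ENSMUSG00000024030), a cholesterol exporter, lies on chromosome 17 from 31057698 to 31115777. Nog (ENSMUSG00000048616), the secreted BMP inhibitor noggin, lies on chromosome 11 from 89300638 to 89302332, and Txnip (ENSMUSG00000038393), a regulator of thioredoxin and glucose uptake, on chromosome 3 from 96557957 to 96561883.

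The first comparison asked how control limbs changed between 3 and 24 h of culture. Cartilage and bone genes rose strongly. Ibsp rose by 7.12 ± 0.25 on the log2 scale, Col10a1 by 2.19 ± 0.19, and the cartilage matrix genes Col2a1, Acan and Comp by 1.30 ± 0.06, 1.47 ± 0.07 and 2.39 ± 0.07 (SE, n = 5 against 5). Ihh, the growth plate hedgehog ligand, rose by 0.90 ± 0.08, and Sp7, a transcription factor of osteoblasts, by 1.13 ± 0.10, while Sox9, the master regulator of cartilage, differed by 0.03 ± 0.07 and was not called (edgeR adjusted p = 0.731). Of 26 measured members of the chondrocyte list 25 rose and none fell, with a median of 1.38. In the hypertrophic chondrocyte list 12 of 16 rose, and in the osteoblast list 14 of 18 rose and 1 fell. Limb patterning factors went the other way, with 28 of 37 lower and 2 higher, among them Lhx9 at -1.09 ± 0.05 and Msx1 at -1.22 ± 0.08. Dividing cell transcripts fell as well. All 26 measured G2/M genes were lower, for example the topoisomerase Top2a at -1.25 ± 0.05, and 27 of 28 G1/S genes were lower, for example the replication factor Mcm5 at -0.82 ± 0.05.

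The same interval moved markers of other cells in the limb. Among 31 skeletal muscle genes 27 rose and 1 fell (adjusted p = 0.0874 with an estimated correlation), with skeletal actin Acta1 up by 2.00 ± 0.07. Of 20 macrophage genes 14 rose and 2 fell (adjusted p = 0.182 with an estimated correlation), and lysozyme Lyz2 was higher by 3.47 ± 0.11. Erythroid genes fell in 11 of 13 cases (adjusted p = 0.182 with an estimated correlation), with the red cell anion exchanger Slc4a1 at -1.80 ± 0.19. Endothelial genes fell in 16 of 21 (adjusted p = 0.182 with an estimated correlation), with the capillary gene Plvap at -2.68 ± 0.15. Stress genes driven by ATF4 fell in 22 of 32 cases and rose in 1 (adjusted p = 0.264 with an estimated correlation), including Atf3 at -1.84 ± 0.11. In all, edgeR called 6227 of 16481 genes, 3147 higher and 3080 lower, of which 599 rose and 486 fell at least 2-fold. The authors' deposited table held 6361 genes at an adjusted p-value under 0.05 for this pair. Adjusted over the list alone, the counts were the same for the chondrocyte, muscle, patterning, G2/M, endothelial, erythroid and macrophage lists, 13 higher and 1 lower for the hypertrophic list and 14 higher and 1 lower for osteoblasts. They were 1 higher and 27 lower for G1/S genes and 2 higher and 24 lower for ATF4 genes. With an estimated correlation, camera kept the chondrocyte (adjusted p = 0.0212), hypertrophic (adjusted p = 0.00489), osteoblast (adjusted p = 0.019), patterning (adjusted p = 0.00489), G2/M (adjusted p = 0.0471) and G1/S (adjusted p = 0.00489) lists.

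Between 24 and 48 h genes of mineralising matrix, cartilage and tendon rose in control limbs. Col10a1 rose by a further 3.23 ± 0.23, Ibsp by 2.60 ± 0.13, Mmp13 by 2.27 ± 0.39 and Col1a1, the main bone and tendon collagen, by 1.44 ± 0.07 (SE, n = 5 against 5), whereas Ihh differed by 0.08 ± 0.10 (edgeR adjusted p = 0.69). The osteoblast list rose in 16 of 19 members with a median of 1.09, the hypertrophic list in 11 of 17, the tendon and fibrous list in 20 of 22 with 1 lower, and the chondrocyte list in 19 of 26 (for chondrocytes, adjusted p = 0.134 with an estimated correlation). Patterning factors kept falling, with 24 of 37 lower and Hoxd12 at -0.84 ± 0.08. Muscle genes rose in 20 of 31 (adjusted p = 0.37 with an estimated correlation) and macrophage genes in 12 of 20, with 1 lower (adjusted p = 0.139 with an estimated correlation). Erythroid genes fell in 7 of 11 (adjusted p = 0.134 with an estimated correlation), with Slc4a1 at -3.19 ± 0.30. Targets of p53 rose in 18 of 25 with 1 lower (adjusted p = 0.124 with an estimated correlation), among them the death receptor Eda2r at 2.21 ± 0.15 and the cell cycle inhibitor Cdkn1a at 1.01 ± 0.11. Of the ATF4 genes 19 of 32 rose (adjusted p = 0.141 with an estimated correlation).

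That interval held 2677 called genes of 16445, 1597 higher and 1080 lower, against 3011 in the authors' deposited table. Without the libraries of 1 sex the count was 1247. Adjusted over the list alone, muscle had 22 higher and 1 lower, macrophages 17 higher and 1 lower, patterning 25 lower and erythroid genes 8 lower, and the other counts stood. Camera with an estimated correlation kept the hypertrophic (adjusted p = 0.0164), osteoblast and patterning (adjusted p = 0.0097 each) and tendon (adjusted p = 0.0426) lists. Over the whole span from 3 to 48 h, 8424 of 16539 genes were called, 4228 higher and 4196 lower (8695 in the authors' deposited table). Ibsp rose by 9.73 ± 0.19, Col10a1 by 5.43 ± 0.24, Mmp13 by 3.74 ± 0.50, Col2a1 by 2.04 ± 0.06 and the cartilage matrix gene Ucma by 6.22 ± 0.37, while 35 of 37 patterning factors were lower and Slc4a1 stood at -4.98 ± 0.17.

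**Figure D1:**
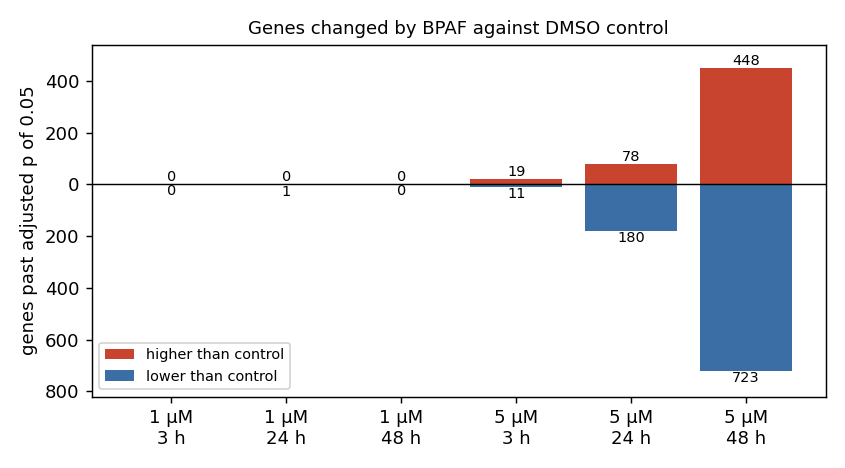
Number of genes called by edgeR at an adjusted p under 0.05 in each comparison of BPAF with control, higher and lower shown on opposite sides of 0 against culture time in hours, for 1 and 5 µM. The 5 µM bars grow from 30 genes at 3 h to 1171 at 48 h, while 1 µM holds 0, 1 and 0 genes.

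At 3 h, 5 µM BPAF raised single genes of the unfolded protein response, Hspa5 and Xbp1 among them, and lowered a few genes, Nog and Abcg1 among them. Hspa5 rose by 0.40 ± 0.06 on the log2 scale, from 625.2 ± 49.6 to 822.2 ± 61.7 CPM (SD, n = 5 each). Xbp1, a transcription factor of that response, rose by 0.48 ± 0.06, the secreted reticulum factor Manf by 0.44 ± 0.07 and the co-chaperone Dnajc3 by 0.42 ± 0.06. Nog fell by 0.60 ± 0.07 on that scale, from 45.05 ± 2.69 to 29.67 ± 2.46 CPM. Lower as well were the cholesterol exporters Abcg1 at -0.79 ± 0.11 and Abca1 at -0.49 ± 0.08, the arrestin-like genes Txnip at -0.51 ± 0.06 and Arrdc4 at -0.54 ± 0.06, and the tubulin Tubb4b at -0.37 ± 0.05. Of 19 reticulum chaperone genes 7 rose over all genes and 16 when adjusted over the list alone, with none lower either way and a median of 0.27 (adjusted p = 0.152 with an estimated correlation, 0.00481 by fry). Sox9 at -0.22 ± 0.05 (edgeR adjusted p = 0.0657) and Col2a1 at -0.10 ± 0.07 were not called. Sox9 was called by DESeq2 (adjusted p = 5.16e-04), limma-voom (adjusted p = 0.0485) and without the low-count filter (edgeR adjusted p = 0.0409). It was called too without control 3 h replicate 4 (edgeR adjusted p = 0.036).

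Other lists were moved by camera at 3 h through small shifts. Glycolysis and hypoxia genes had a median of -0.14 with 0 of 33 called over all genes and 11 lower adjusted over the list alone (adjusted p = 0.518 with an estimated correlation). Cholesterol synthesis genes had a median of 0.22 with 0 of 25 called and 11 higher adjusted over the list alone (adjusted p = 0.577 with an estimated correlation). Skeletal muscle (30 genes, median 0.03) and the estrogen-responsive list (18 genes, of which Xbp1 was higher, also adjusted over the list alone) were not called. In all, edgeR called 30 of 16651 genes, 19 higher and 11 lower, none of them by 2-fold, while 113 passed in the authors' deposited table. The smallest adjusted p were those of Nog and Arrdc4, 2.15e-04 each. Leaving out control 3 h replicate 1 gave 16 genes, control 3 h replicate 5 gave 19, 5 µM 3 h replicate 2 gave 15 and 5 µM 3 h replicate 5 gave 18. The excess of higher calls was not kept either, with 40 higher and 39 lower without the low-count filter (79 in all) and 52 and 63 by DESeq2 (115). Calls numbered 12 higher and 11 lower with the Y-linked covariate and 14 and 14 without libraries of 1 sex. Abca1 was not called with the Y-linked covariate, at -0.44 (edgeR adjusted p = 0.0655).

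By 24 h, 5 µM BPAF had lowered genes of contractile muscle and single genes of macrophages and hypertrophic cartilage. Myh3 fell by 0.78 ± 0.07 on the log2 scale, with the fast troponin Tnnt3 at -0.88 ± 0.08 and the calcium store protein Casq2 at -0.59 ± 0.07 (SE, n = 5 against 5). Col10a1 fell by 1.64 ± 0.20, from 23.39 ± 6.3 to 7.52 ± 2.25 CPM, with Ibsp at -2.00 ± 0.30, while Fgfr3, the receptor that restrains chondrocyte growth, rose by 0.55 ± 0.07. The largest fall among genes named here was that of Atp1b4, a muscle membrane protein, at -2.14 ± 0.26, and Abcg1 stood at -1.59 ± 0.10 with the lipid regulator Srebf1 at -0.55 ± 0.07. The collagenase Mmp13 was higher by 2.18 ± 0.49 and the macrophage elastase Mmp12 by 2.60 ± 0.44. The level of Mmp13 was low, at 2.51 CPM in 5 µM 24 h replicate 1 and 1.06 CPM in the next highest library of that group. Sox9, Col2a1, Acan, Ihh and Runx2 were not called.

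Grouped by list, 16 of 29 muscle genes fell at 24 h and none rose (24 lower adjusted over the list alone, median -0.53, adjusted p = 0.0718 with an estimated correlation). Macrophage genes fell in 3 of 20 cases (10 adjusted over the list alone, adjusted p = 0.219 with an estimated correlation), among them the chemokine receptor Cx3cr1 at -1.16 ± 0.19 and Lyz2 at -0.64 ± 0.12. In the endothelial list 2 of 20 fell (4 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation), and among 12 smooth muscle and pericyte genes 1 fell, Acta2 at -0.83 ± 0.10 (5 adjusted over the list alone, adjusted p = 0.218 with an estimated correlation). Reticulum chaperones rose in 5 of 19 cases (15 adjusted over the list alone, adjusted p = 0.0718 with an estimated correlation), with Hspa5 at 0.36 ± 0.05 and calreticulin Calr at 0.40 ± 0.06. Targets of p53 rose in 4 of 25 cases (11 adjusted over the list alone, adjusted p = 0.19 with an estimated correlation), with the cyclin Ccng1 at 0.56 ± 0.10. ATF4 genes rose in 5 of 32 cases (15 adjusted over the list alone, adjusted p = 0.219 with an estimated correlation). In the FGF list 1 gene rose and 1 fell of 20 (1 higher and 8 lower adjusted over the list alone, adjusted p = 0.171 with an estimated correlation). Camera no longer called it without 5 µM 24 h replicate 5 (adjusted p = 0.0662) or with the Y-linked covariate (adjusted p = 0.0893). In the hypertrophic list 1 gene rose and 3 fell of 17, the same adjusted over the list alone (adjusted p = 0.219 with an estimated correlation). Camera no longer called it with the replicate number as a block (adjusted p = 0.0744), where numbers paired the libraries. Its call was also lost with the Y-linked covariate (adjusted p = 0.0843), and without the pair of 24 h libraries highest in haemoglobin reads (adjusted p = 0.241). Leaving out control 24 h replicate 1 (adjusted p = 0.0569), control 24 h replicate 5 (adjusted p = 0.115) or 5 µM 24 h replicate 5 (adjusted p = 0.0829) ended it as well.

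In total 258 of 16433 genes were called at 24 h and 5 µM, 78 higher and 180 lower, of which 7 rose and 29 fell at least 2-fold (513 in the authors' deposited table). Replicate numbers paired the libraries here, and with the replicate number as a block 655 genes were called. The count rested on single libraries: without control 24 h replicates 1, 2, 3 and 4 it was 128, 132, 131 and 148, without 5 µM 24 h replicates 1, 2 and 3 it was 109, 133 and 161, and without 5 µM 24 h replicate 5 it was 498. That last library and control 24 h replicate 5 had the highest haemoglobin shares at 24 h, and without both 514 genes were called and Mmp13 was not (2.06, edgeR adjusted p = 0.0529), while 64 were called without libraries of 1 sex, 10 higher and 54 lower. The Mmp13 call was lost without any of control 24 h replicates 1 to 5 or 5 µM 24 h replicates 1 and 2 (edgeR adjusted p = 0.0529 to 0.12). The Mmp12 call was lost by limma-voom, at 2.49 (limma adjusted p = 0.052). Without the libraries of 1 sex Mmp13 at 2.29 (edgeR adjusted p = 0.239), Mmp12 at 2.77 (edgeR adjusted p = 0.0753) and Ccng1 at 0.52 (edgeR adjusted p = 0.162) were not called, with fewer libraries fitted.

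At 48 h the fall of muscle genes with 5 µM BPAF was general. Pax7 fell by 1.99 ± 0.13 on the log2 scale, from 14.76 ± 1.26 to 3.77 ± 0.58 CPM, with the slow myosin Myh7 at -1.75 ± 0.13, the sarcomere ruler Neb at -0.996 ± 0.08 and the calcium release channel Ryr1 at -0.85 ± 0.07 (SE, n = 5 against 5). Of 30 measured muscle genes 28 fell and none rose, with a median of -0.996, and the count was 28 adjusted over the list alone (adjusted p = 0.146 with an estimated correlation, 4.77e-04 by fry). The members that were not called were the determination factor Myod1 at -0.20 ± 0.10 and the acetylcholine receptor gene Chrna1 at -0.20 ± 0.10, which are given here after their values were seen. Myod1 was called without control 48 h replicate 1 (edgeR adjusted p = 0.0251). Among the named genes with the largest falls were further genes of striated muscle, Abra at -3.79 ± 0.30, Atp1b4 at -3.59 ± 0.22 and Myh7b at -2.65 ± 0.17. The mean level of the muscle list was 7.40 ± 0.249 log2 CPM in control and 6.44 ± 0.134 in 5 µM libraries (SD, n = 5 each; two-sided exact permutation p = 0.00794, the smallest possible, 0.0143 adjusted over 18 tests), and every 5 µM library lay below every control library.

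**Figure D2:**
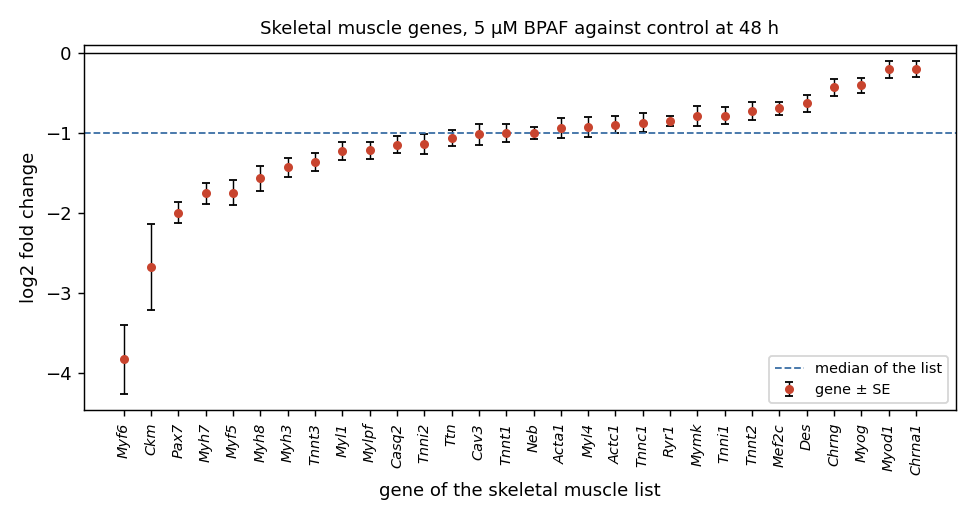
Log2 fold change of each measured skeletal muscle gene for 5 µM BPAF against control at 48 h, with its standard error, n = 5 libraries per group. Values run from -3.82 for Myf6, a muscle regulatory factor singled out after its value was seen, to -0.20 for Myod1 and Chrna1, around a median of -0.996.

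Members of the macrophage, endothelial and smooth muscle lists were also lower at 48 h. Macrophage genes fell in 11 of 20 cases (18 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), with the growth factor receptor Csf1r at -1.19 ± 0.12 and Lyz2 at -1.05 ± 0.10. Endothelial genes fell in 5 of 20 cases (11 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation), with the vascular cadherin Cdh5 at -0.51 ± 0.08. Smooth muscle and pericyte genes fell in 5 of 12 cases (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), with the pericyte gene Rgs5 at -1.77 ± 0.16. Glycolysis and hypoxia genes fell in 14 of 33 cases (20 adjusted over the list alone, adjusted p = 0.513 with an estimated correlation), with the aldolase Aldoa at -0.60 ± 0.09 and Gapdh at -0.42 ± 0.08. Nuclear genes of oxidative phosphorylation fell in 18 of 92 cases and rose in 1 (24 lower and 1 higher adjusted over the list alone, adjusted p = 0.422 with an estimated correlation). Among its members that fell were the cytochrome oxidase subunits of striated muscle, Cox6a2 at -1.62 ± 0.17 and Cox8b at -1.87 ± 0.41.

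Many stress response genes were higher at 48 h. Trib3 rose by 1.43 ± 0.16, from 12.9 ± 1.27 to 35.39 ± 10.3 CPM, the leucine sensor Sesn2 by 0.67 ± 0.10 and the amino acid transporter Slc7a5 by 0.53 ± 0.08. Of 32 ATF4 genes 20 rose and none fell (23 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation). Reticulum chaperones rose in 14 of 19 cases (18 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), with Hspa5 at 0.43 ± 0.06 and the disulfide isomerase Pdia4 at 0.44 ± 0.06. Targets of p53 rose in 16 of 25 cases (19 adjusted over the list alone, adjusted p = 0.146 with an estimated correlation), with the death receptors Fas at 1.15 ± 0.19 and Tnfrsf10b at 0.60 ± 0.09 and the cyclin Ccng1 at 0.70 ± 0.11. NRF2 genes rose in 4 of 21 cases (8 higher and 1 lower adjusted over the list alone, adjusted p = 0.213 with an estimated correlation), with haem oxygenase Hmox1 at 0.61 ± 0.11 and sulfiredoxin Srxn1 at 0.56 ± 0.11.

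**Figure D3:**
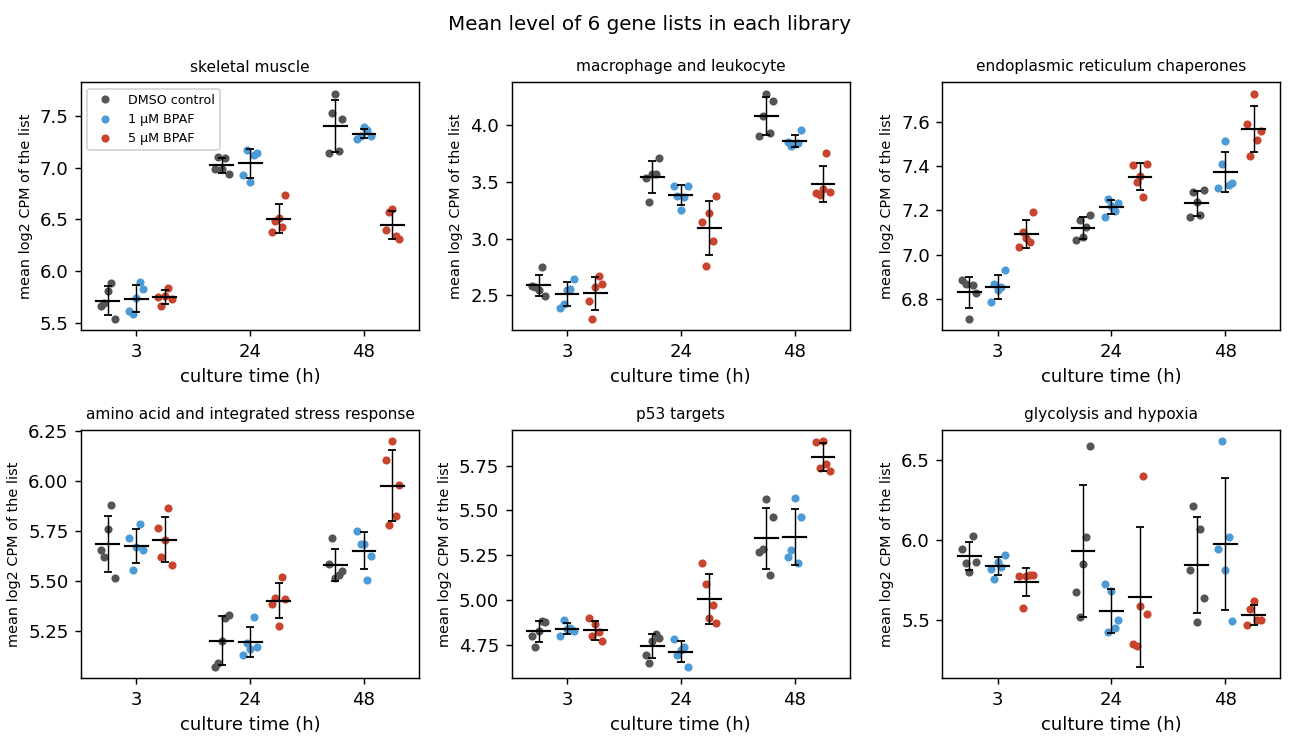
Mean log2 CPM of the members of selected gene lists in each library against culture time in hours, for control, 1 µM and 5 µM. Members with a mean CPM of at least 2 are used. Points are libraries, and bars are group means and SD (n = 5). At 48 h the skeletal muscle mean was 7.40 in control and 6.44 with 5 µM, and the chaperone mean was 7.23 in control and 7.57 with 5 µM.

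Single skeletal genes changed at 48 h, while the cartilage and bone lists were not called. Ibsp fell by 1.34 ± 0.23 on the log2 scale, with the cartilage matrix gene Ucma at -1.28 ± 0.24 and Mef2c, a transcription factor of hypertrophy and of muscle, at -0.69 ± 0.08, while Fgfr3 rose by 0.48 ± 0.09 and the bone matrix proteoglycan Omd by 0.89 ± 0.12. Col10a1 fell by 1.17 ± 0.34 from 219.9 ± 78.3 to 99.22 ± 63 CPM (edgeR adjusted p = 0.0423), a call lost without control 48 h replicate 1, 2, 4 or 5 or 5 µM 48 h replicate 2, 4 or 5 (edgeR adjusted p = 0.0516 to 0.105) and by DESeq2 (adjusted p = 0.109). Mmp13 rose by 1.43 ± 0.36 (edgeR adjusted p = 0.021), a call lost without control 48 h replicate 5 (edgeR adjusted p = 0.059) or 5 µM 48 h replicate 3 (edgeR adjusted p = 0.0733) and by limma-voom (adjusted p = 0.074). Col2a1 at 0.24 ± 0.07 (edgeR adjusted p = 0.0607), Acan at 0.15 ± 0.07, Ihh at 0.33 ± 0.10, Sox9 at -0.02 ± 0.07 and Runx2 at 0.01 ± 0.08 were not called. For Col2a1 and Ihh this depended on the setting. Col2a1 was called by DESeq2 (adjusted p = 0.00901), limma-voom (adjusted p = 0.0494), and with all libraries in 1 model (edgeR adjusted p = 0.0134). It was called too with the replicate number as a block (edgeR adjusted p = 0.0273) and without 5 µM 48 h replicate 2 (edgeR adjusted p = 0.0236). Ihh was called by DESeq2 (adjusted p = 0.0257) and without the low-count filter (edgeR adjusted p = 0.0252). It was also called with the replicate number as a block (edgeR adjusted p = 0.00681). The call was made too without control 48 h replicate 5 (edgeR adjusted p = 0.0171) or 5 µM 48 h replicate 4 (edgeR adjusted p = 0.0406). The chondrocyte (1 higher and 1 lower of 26), hypertrophic (2 higher and 3 lower of 17) and osteoblast (3 higher and 2 lower of 21) lists were not called. Adjusted over the list alone, these had 2 higher and 1 lower, 4 higher and 4 lower, and 4 higher and 2 lower members. The inhibitor of bone formation Sost was lower at -2.83 ± 0.43 and the growth factor gene Fgf4 stood at -1.97 ± 0.33. In all, 1171 of 16345 genes were called, 448 higher and 723 lower, of which 31 rose and 200 fell at least 2-fold (1521 in the authors' deposited table). With all libraries in 1 model, which also scales over all 45, the excess of lower calls was gone, with 899 higher and 846 lower.

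**Figure D4:**
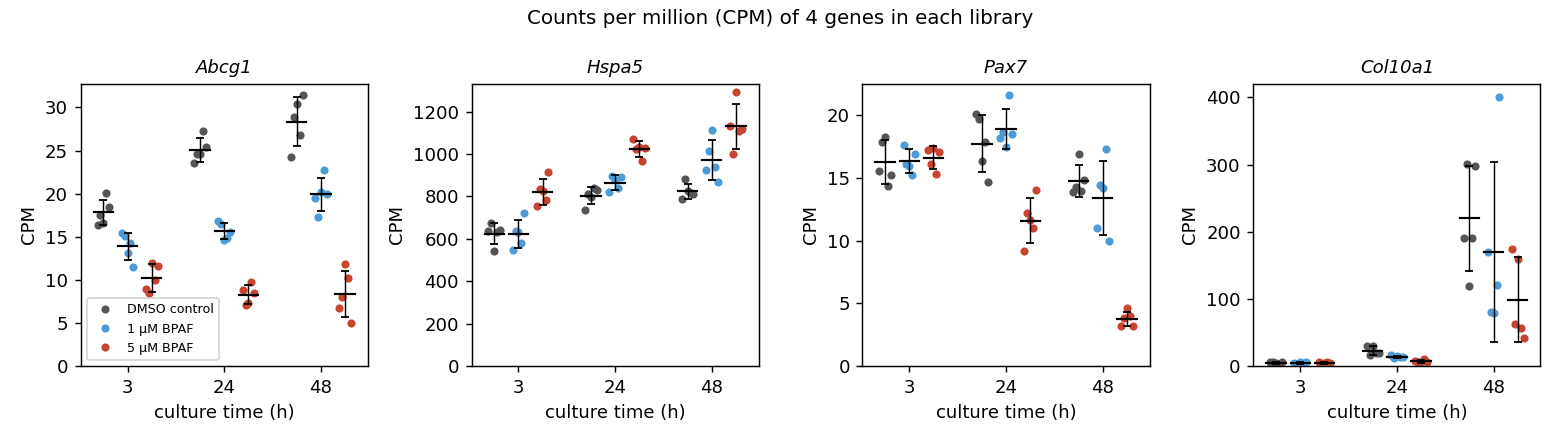
CPM of Abcg1, Hspa5, Pax7 and Col10a1 in each library against culture time in hours for control, 1 µM and 5 µM, with group means and SD (n = 5). Pax7 stood at 14.76 in control and 3.77 with 5 µM at 48 h, and Abcg1 at 25.09 in control, 15.67 with 1 µM and 8.29 with 5 µM at 24 h.

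At 1 µM single genes hardly moved. Abcg1 fell by 0.68 ± 0.07 on the log2 scale at 24 h, from 25.09 ± 1.41 to 15.67 ± 0.954 CPM (SD, n = 5 each; edgeR adjusted p = 0.00133), and was the only gene called in the 3 comparisons of 1 µM with control. Without the libraries of 1 sex its fold change was -0.72, and with fewer libraries it was not called (edgeR adjusted p = 0.0738). At 3 h edgeR called 0 of 16631 genes, with 424 at an unadjusted p under 0.05 where chance gives 832, and DESeq2 and limma-voom also called 0. Without control 3 h replicate 4 edgeR called 1 gene. At 24 h 439 of 16439 genes had an unadjusted p under 0.05, and 2 genes were called by DESeq2, 2 with the replicate number as a block, where numbers paired the libraries, and 2 in the authors' deposited table. At 48 h edgeR called 0 of 16479 genes (621 at an unadjusted p under 0.05, smallest adjusted p 0.647), limma-voom 0 and DESeq2 4, and 4 genes passed in the authors' deposited table. With the library code number as a block, where those numbers paired the 48 h libraries, edgeR also called 0, with 1211 genes at an unadjusted p under 0.05 where chance gives 824. Leaving out the 3 h library whose labels also name another compound left the 3 h count at 0.

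Camera found shifts of whole lists at 1 µM whose members were not called one by one. At 24 h the glycolysis and hypoxia list had a median of -0.34 with 19 of 33 lower adjusted over the list alone (adjusted p = 0.508 with an estimated correlation), at a mean level of 5.55 ± 0.137 log2 CPM against 5.93 ± 0.415 in control (SD, n = 5 each). Control 24 h replicate 5 stood at 6.59, and without it the difference in level went from -0.38 to -0.21. At 48 h camera called it in the other direction, with a median of 0.12, 0 of 33 called adjusted over the list alone (adjusted p = 0.958 with an estimated correlation) and a level of 5.97 ± 0.411 against 5.84 ± 0.3. That call was lost without control 48 h replicate 1 (adjusted p = 0.176), 3 (0.669) or 5 (0.377) or 1 µM 48 h replicate 1 (0.079) or 4 (0.115). Its direction turned without 1 µM 48 h replicate 2 (0.486), with the Y-linked covariate (0.431) and without libraries of 1 sex (0.015). Muscle genes had a median of -0.10 at 48 h with 0 of 31 called adjusted over the list alone (adjusted p = 0.958 with an estimated correlation). Camera lost that list without control 48 h replicate 2 (adjusted p = 0.145) or 3 (0.885) or 1 µM 48 h replicate 1 (0.0984), and its direction turned without libraries of 1 sex (0.979). Reticulum chaperones had a median of 0.10 at 24 h with 0 of 19 higher adjusted over the list alone (adjusted p = 0.366 with an estimated correlation) and of 0.14 at 48 h with 7 of 19 higher adjusted over the list alone (adjusted p = 0.349 with an estimated correlation). Macrophage genes had medians of -0.19 at 24 h, with 0 of 20 lower adjusted over the list alone (adjusted p = 0.508 with an estimated correlation), and -0.23 at 48 h, where 2 of 20 were lower adjusted over the list alone (adjusted p = 0.349 with an estimated correlation). At 3 h the chondrocyte list had a median of -0.11 with 0 of 25 lower adjusted over the list alone (adjusted p = 0.896 with an estimated correlation). Cholesterol synthesis genes had medians of 0.13, 0.12 and 0.10 at 3, 24 and 48 h, with 0 of 25 higher adjusted over the list alone each time (adjusted p = 0.896, 0.508 and 0.349 with an estimated correlation). At 48 h nuclear oxidative phosphorylation genes had a median of -0.15 with 2 of 92 lower adjusted over the list alone (adjusted p = 0.349 with an estimated correlation).

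Set directly against 1 µM, 5 µM BPAF raised single reticulum chaperones already at 3 h. Hyou1, a reticulum chaperone, was higher by 0.32 ± 0.04, Xbp1 by 0.41 ± 0.06, Dnajc3 by 0.40 ± 0.06 and Hspa5 by 0.40 ± 0.07 (SE, n = 5 against 5), the arrestin-like Arrdc3 was higher by 0.31 ± 0.05 and Arrdc4 was lower at -0.40 ± 0.06. These 6 were all the genes called among 16681, and Nog at -0.46 ± 0.08 was not (edgeR adjusted p = 0.052). Nog was called with the replicate number as a block (edgeR adjusted p = 0.00485), by DESeq2 (adjusted p = 4.54e-04) and without the low-count filter (edgeR adjusted p = 9.24e-04). It was also called with all libraries in 1 model (edgeR adjusted p = 0.0374) and without 1 µM 3 h replicate 3 (edgeR adjusted p = 0.016). In the chaperone list 4 of 19 rose (16 higher and 1 lower adjusted over the list alone, adjusted p = 0.0691 with an estimated correlation). With the replicate number as a block, where numbers paired the libraries, 50 genes were called, 28 higher and 22 lower. Among other splits that part each pair, the highest count with the block was 31. Without 1 µM 3 h replicate 4 only 1 gene was left and without 5 µM 3 h replicate 5 only 3 were. Of the 6, Hyou1 was called whichever library was left out, and Xbp1 and Dnajc3 were lost without 1 µM 3 h replicate 4 alone (edgeR adjusted p = 0.0636 each). Hspa5 was lost without any library of the pair of groups other than 1 µM 3 h replicate 5 and 5 µM 3 h replicate 1 (edgeR adjusted p = 0.0561 to 0.149), and Arrdc3 without any other than 1 µM 3 h replicate 2 and 5 µM 3 h replicate 1 (edgeR adjusted p = 0.056 to 0.157). Arrdc4 was lost without 1 µM 3 h replicate 3, 4 or 5 or 5 µM 3 h replicate 2, 4 or 5 (edgeR adjusted p = 0.0629 to 0.129). With the Y-linked covariate Hspa5 (edgeR adjusted p = 0.0773) and Arrdc3 (edgeR adjusted p = 0.0899) were lost. With all libraries in 1 model Arrdc3 was lost too (edgeR adjusted p = 0.255).

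The same contrast at 24 h lowered muscle genes. Myh3 was lower at -0.77 ± 0.07 and Tnnt3 at -0.91 ± 0.09, and 18 of 30 muscle genes fell (25 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation). Targets of p53 rose in 6 of 25 cases (12 adjusted over the list alone, adjusted p = 0.108 with an estimated correlation), with Eda2r at 1.22 ± 0.23 and Ccng1 at 0.57 ± 0.10. Col10a1 at -0.92 ± 0.17 (edgeR adjusted p = 0.296 with all libraries in 1 model) and Ibsp at -1.66 ± 0.28 were lower, Fgfr3 at 0.48 ± 0.06 higher and Spry1, an inhibitor of FGF signalling, lower at -0.42 ± 0.07. Macrophage genes fell in 1 of 20 cases, Cx3cr1 at -0.84 ± 0.15 (4 adjusted over the list alone, adjusted p = 0.327 with an estimated correlation). The count was 196 of 16496 genes, 40 higher and 156 lower (106 and 233 by DESeq2, and 199 and 354 without the 24 h libraries high in haemoglobin). Without 1 µM 24 h replicates 2, 4 and 5 it was 103, 101 and 107, without 5 µM 24 h replicate 1 it was 95 and without 5 µM 24 h replicate 5 it was 553.

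Between the doses at 48 h the muscle list was lower throughout, with 30 of 30 genes called (30 adjusted over the list alone, median -0.89, adjusted p = 0.0762 with an estimated correlation), Myh3 at -1.28 ± 0.06 and Myh7 at -1.66 ± 0.08. Single cartilage genes were higher with 5 µM than with 1 µM. Col2a1 rose by 0.34 ± 0.07 and Acan by 0.27 ± 0.06 (for Acan, edgeR adjusted p = 0.0516 with all libraries in 1 model), and 6 of 26 chondrocyte genes rose (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.477 with an estimated correlation). Targets of p53 rose in 15 of 25 cases (18 adjusted over the list alone, adjusted p = 0.195 with an estimated correlation), with the cell death gene Bbc3 at 0.73 ± 0.12, and ATF4 genes in 13 of 32 (22 adjusted over the list alone, adjusted p = 0.361 with an estimated correlation), with Trib3 at 1.07 ± 0.17. Macrophage genes fell in 8 of 20 cases (10 lower and 1 higher adjusted over the list alone, adjusted p = 0.195 with an estimated correlation) and glycolysis genes in 14 of 33 (23 adjusted over the list alone, adjusted p = 0.477 with an estimated correlation), with the lactate exporter Slc16a3 at -1.27 ± 0.25. The count was 974 of 16349 genes, 358 higher and 616 lower (628 and 671 with all libraries in 1 model), and 1618 with the library code number as a block, where those numbers paired the libraries.

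Whether the effect of 5 µM BPAF differed between times was tested directly. Between 3 and 24 h the effect on muscle genes dropped, with Myom2 and Myom1, proteins of the sarcomere's M band, at -1.24 ± 0.14 and -1.10 ± 0.14, and Myh3 at -0.88 ± 0.10 (SE, 20 libraries). Acta2 at -0.86 ± 0.13, the actin-binding Ablim3 at -0.73 ± 0.11 and the creatine synthesis gene Gatm at -0.65 ± 0.09 followed. Of 31 muscle genes 9 passed and 23 adjusted over the list alone, all lower (median -0.50, adjusted p = 0.0282 with an estimated correlation). The FGF list (1 higher and 2 lower of 21, 3 and 8 adjusted over the list alone, median -0.17), the p53 list (1 higher of 25, 7 adjusted over the list alone, median 0.21) and the Schwann cell and neural list (0 of 18, 1 lower adjusted over the list alone, median -0.15) moved too, each with adjusted p = 0.0282 with an estimated correlation. Macrophage genes had a median of -0.40 with 0 of 20 called (3 lower adjusted over the list alone, adjusted p = 0.306 with an estimated correlation). In all 59 of 17535 genes passed, 11 higher and 48 lower (2 and 30 with the Y-linked covariate, 0 and 16 without libraries of 1 sex). Without control 3 h replicates 2 and 5 the count was 34 and 35, without 5 µM 3 h replicates 3 and 4 it was 37 and 35, without control 24 h replicates 2 and 3 it was 35 and 39, and without 5 µM 24 h replicates 1 and 5 it was 30 and 109.

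From 24 to 48 h the 5 µM effect on Pax7 dropped by a further 1.38 ± 0.18 and that on Myh7b stood at -1.98 ± 0.28 (SE, 20 libraries), calls that held whichever library was left out. Of 31 muscle genes 2 passed (18 lower adjusted over the list alone, median -0.46, adjusted p = 0.183 with an estimated correlation). In all 12 of 17315 genes passed, 1 higher and 11 lower. The count was 3 and 2 without control 24 h replicates 2 and 3, 6 without control 24 h replicate 5, 3 and 7 without 5 µM 24 h replicates 3 and 4, 6 without control 48 h replicate 3, 6 without control 48 h replicate 5, 6 without 5 µM 48 h replicate 1 and 2 without 5 µM 48 h replicate 5. For 1 µM no difference between times was called by edgeR among 17495 genes from 3 to 24 h (446 at an unadjusted p under 0.05) or 17323 genes from 24 to 48 h (509 at an unadjusted p under 0.05), and DESeq2 and limma-voom called 0 in both.

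The genes called with 5 µM at 24 and 48 h, in libraries that share no control, overlapped widely. Of 78 genes higher at 24 h 58 were also higher at 48 h, where independent lists would share 2.1, and of 178 genes lower at 24 h and tested at both times 158 were lower at 48 h, where independent lists would share 7.9. None of them was called in opposite directions. From 3 h, 13 of 19 higher genes were higher at 48 h (0.5 for independent lists) and 1 was lower, and 5 of 11 lower genes were lower (0.5) and 2 were higher. The 1 and 5 µM fold changes at each time use the same control libraries. At 48 h they correlated at 0.413 over 12025 genes, against 0.496 in simulations of unchanged groups and 0.131 as the mean over split controls, and their covariance was 0.013 against 0.00679 simulated, an excess of 0.00618. At 24 h the correlation was 0.469 (0.501 simulated, -0.018 with split controls) with an excess covariance of 6.08e-04, and at 3 h it was 0.524 (0.499 simulated, -0.013 with split controls) with an excess of 0.00126.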

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

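The tests of differences between times were planned, while the tests for libraries far from their group, the tests of explanations and the other splits of the samples were chosen only after the results were seen.

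Skeletal muscle genes were lower at 5 µM and 48 h by a median of -0.996. The lowest control library lay 0.539 log2 CPM above the highest 5 µM library, with a control SD of 0.249 (two-sided exact permutation p = 0.00794, the smallest possible). The list was singled out for its fall in these same libraries. Their separation alone therefore cannot decide on uneven amounts of muscle in the pooled limbs. In the separate 24 h libraries the lowest control (6.94) also lay above the highest 5 µM library (6.734), while at 3 h the groups overlapped. Uneven amounts would have to lie the same way at 24 and 48 h. The choice between TMM and DESeq2 size factors mattered little, since the list's median was -0.989 with the latter. This cannot decide on scaling as such, because both scalings were nearly the same here, with medians over all genes of -0.0019 and 0.005. An equal loss of all muscle cells was argued against, because 14 of 30 members lay more than 3 SE from the list's median of -0.996. Normal errors around the median would give 0.081, a number too low for SE that rest on few libraries. Of the 14, 8 lay below the median and 6 above. Those above included Mef2c, also a factor of hypertrophy, and Des, also in the smooth muscle list. Expression outside skeletal muscle could hold up such members even in an equal loss. Myf6 at -3.82 and Pax7 at -1.99 lay far below and Myog at -0.40 above. Lower expression in muscle cells and a loss that differs between kinds of muscle cells both stay open, and either may be a biological effect of the dose.

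Glycolysis and hypoxia genes were lower at 5 µM and 48 h in 14 of 33 cases. Differences in culture conditions between bottles, such as oxygen, cannot be told apart from an effect of the dose here. The list levels of the libraries overlapped, with 5.48 to 6.21 log2 CPM in control and 5.47 to 5.61 with 5 µM, and the two-sided exact permutation p was 0.0476 (0.0659 adjusted over 18 tests). At 3 h each 5 µM library (highest 5.782) lay narrowly below each control library (lowest 5.798). The difference of means was -0.16 with a control SD of 0.088 (two-sided exact permutation p = 0.00794, 0.0143 adjusted). Camera had already called the list lower in these libraries, with no member called over all genes. The levels at 3 h are thus no separate evidence, and differences between bottles stay open at 3 and 48 h. Single libraries stood apart, with 5 µM 24 h replicate 4 at 6.40 (nearest 5.59) and 5 µM 3 h replicate 2 at 5.58 (nearest 5.77).

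Titles and library codes of 1 µM 48 h replicates 1 and 2 give each other's numbers. Pairing by library code ranked 1 among 120 pairings with control 48 h (mean r 0.313, against 0.187 and rank 6 by title) and also 1 with 5 µM 48 h (0.256, against 0.225 and rank 2 by title), which is consistent with exchanged titles. These correlations are across genes, which are not independent replicates. No count without a block depends on this numbering, and no biological explanation was tested.

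Of 180 sets of 5 libraries tested, 13 held a library far from the rest, while chance gives about 1 in 20, or 9. The 5 µM 3 h replicate 2 and the 1 µM 48 h replicate 5 were far in more than 1 set. Haemoglobin reads were 0.251% in control 24 h replicate 5 (nearest 0.149) and 0.0396% in 5 µM 48 h replicate 1 (nearest 0.0553), and the 10 most abundant genes took 4.94% of reads in control 3 h replicate 4 (nearest 4.49). Myod1 stood at 137.8 CPM in 5 µM 24 h replicate 5 (nearest 111) and at 107.3 CPM in 1 µM 48 h replicate 2 (nearest 115.2). Col10a1 was 400.7 CPM in 1 µM 48 h replicate 5 (nearest 169.7), Mmp13 was 2.51 CPM in 5 µM 24 h replicate 1 (nearest 1.06) and Col2a1 was 9096 CPM in control 48 h replicate 3 (nearest 10720). Nog was 25.34 CPM in 5 µM 3 h replicate 2 (nearest 30.27). The macrophage list level was 3.96 log2 CPM in 1 µM 48 h replicate 5 (nearest 3.85) and 3.76 in 5 µM 48 h replicate 4 (nearest 3.44).

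The effect of 5 µM differed between 3 and 24 h in 59 genes, a count of 109 without 5 µM 24 h replicate 5 and 30 without 5 µM 24 h replicate 1, with the other libraries that moved it named in the report. The genes with the smallest p were Myom2 (-1.24), Myh3 (-0.88), Myom1 (-1.10), Gatm (-0.65), Acta2 (-0.86) and Ablim3 (-0.73), as log2 differences of effects. Of the lists, skeletal muscle (median -0.50), the FGF pathway (-0.17), Schwann cell and neural genes (-0.15) and p53 targets (0.21) differed with an estimated correlation. Between 24 and 48 h 12 genes differed, led by Pax7 (-1.38) and Myh7b (-1.98). The next were Tmod1 (-1.07), which caps actin filaments, Xirp1 (-1.28), an actin-binding protein of muscle, Frem2 (-0.80), a basement membrane protein, and Rgs5 (-1.26). Tmod1 was lost without control 24 h replicate 3 (edgeR adjusted p = 0.0613) or 5 µM 48 h replicate 5 (edgeR adjusted p = 0.0564). Xirp1 was lost without control 24 h replicate 2 or 3, 5 µM 24 h replicate 3 or 5 µM 48 h replicate 5 (edgeR adjusted p = 0.0535 to 0.0627). Frem2 was lost without control 24 h replicate 2 or 3, 5 µM 24 h replicate 3 or 4, or 5 µM 48 h replicate 1 or 5 (edgeR adjusted p = 0.0524 to 0.0932). Rgs5 was lost without control 24 h replicate 2, 3 or 5, 5 µM 24 h replicate 3, control 48 h replicate 5, or 5 µM 48 h replicate 1 or 5 (edgeR adjusted p = 0.0548 to 0.0932). Without libraries of 1 sex Tmod1, Xirp1, Frem2 and Rgs5 were lost (edgeR adjusted p = 0.111, 0.152, 0.141 and 0.295). Without the 24 h libraries high in haemoglobin Xirp1 and Rgs5 were lost (edgeR adjusted p = 0.0769 and 0.0863). By limma-voom Xirp1 was lost (limma adjusted p = 0.0654).

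Other splits of the same libraries were drawn, 50 for each comparison of a pair of groups and 40 for each difference between times, the real one included. The real split called more genes than each other split for 5 µM against control at 3 h (30 genes, highest other split 5), 24 h (258, highest 1) and 48 h (1171, highest 1). It also did for 5 µM against 1 µM at 24 h (196, highest 113) and 48 h (974, highest 1). The same was true of the control times (6227, highest 0, then 2677, highest 17, and 8424, highest 1). It was true too of the differences in the 5 µM effect (59, highest 0, and 12, highest 1). The smallest share these splits can give is 1 of 50 or 1 of 40, and shares were not adjusted over comparisons. For 5 µM against 1 µM at 24 h chance stays open, since the real count was 95 without 5 µM 24 h replicate 1. All of this holds for the number of called genes. By the number of genes at an unadjusted p under 0.05 chance cannot be excluded for 5 µM against control at 24 h (1902 genes, reached by 5 of 50 splits, highest other 2658). The same holds for 5 against 1 µM at 24 h (1598 genes, reached by 4 of 50 splits, highest other 2985). Nor can it be for the differences in the 5 µM effect (1325, reached by 4 of 40 splits, highest 1795, and 806, reached by 13, highest 1777). For 5 µM against 1 µM at 3 h, 2 of 50 splits gave as many as the real 6 genes, and the highest other gave 17, several times the real count, which points to a structure of these samples beside dose. Chance cannot be excluded for 1 µM against control at 24 h (1 gene, reached by 3 splits, highest other 1). Where the real count is 0 each split reaches it, so the splits decide nothing for 1 µM against control at 3 h (50 of 50 splits, highest other 20) and 48 h (50 of 50, highest 1) or for the differences in the 1 µM effect (40 of 40, highest 1, and 40 of 40, highest 2). The 20 genes of a split at 3 h with 1 µM likewise point to a structure of the samples.

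Those splits were fitted without a block, and most part only some pairs of libraries. Where numbers paired the libraries, the real split was set against the 15 others that part each pair, and 16 splits are too few for a share under 0.05. For 5 µM against control at 24 h 1902 genes had an unadjusted p under 0.05 without the block, reached by 5 of the 50 splits of any kind (highest other 2658) but by none of these 15 (highest 1162). With the replicate number as a block there were 2682 (highest 1701), with 655 called (highest 2). For 5 against 1 µM at 48 h the library code number as a block gave 3691 (highest 1432), with 1618 called (highest 0). For 5 against 1 µM at 3 h the 989 genes without the block were reached by 10 of the 50 splits (highest 1799), and 1170 was the highest of the 15. With the block there were 1394 (highest 1709), with 50 called (highest 31). For 1 µM against control the block gave 596 (highest 1584) at 24 h, with 2 called (highest 4), and 1211 (highest 1929) at 48 h, with 0 called (highest 15).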

How the results depend on the processing

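Leaving out libraries of tissue of 1 sex and leaving out the 24 h libraries high in haemoglobin were chosen after the data were seen, and the other tests were planned. For 5 µM against control at 48 h the count of 1171 genes stayed between 912 and 1745 under every alternative run. DESeq2 size factors moved no count by over 1.5 times and no share of higher calls by over 10 percentage points. Other alternatives moved that share further for 5 µM against control at 3, 24 and 48 h, for 5 against 1 µM at 24 and 48 h and for the 24 less 3 h difference of the 5 µM effect, with the splits in the report. For 5 against 1 µM at 3 h (5 higher and 1 lower) they were 15 and 10 without the low-count filter, 25 and 15 by DESeq2, 7 and 3 by limma-voom, 7 and 4 with all libraries in 1 model and 28 and 22 with the block. Single libraries left out are not counted here. Pseudocounts on normalized values did not apply, since counts were tested. A result that was not called has no direction and counts as kept while uncalled. The cause of the changes given here was not tested, except that fewer libraries were fitted where some are left out.

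By DESeq2 the counts were 115 for 5 µM against control at 3 h and 517 at 24 h, 2 for 1 µM at 24 h and 4 at 48 h, 40 and 339 for 5 against 1 µM at 3 and 24 h, and 149 and 50 for the differences of the 5 µM effect at 24 less 3 h and 48 less 24 h. In the simulation for 5 µM against control at 48 h DESeq2 called 30 unchanged genes against 9 by edgeR, so its higher counts may hold more false calls. Limma-voom gave 10 for 5 against 1 µM at 3 h and 7 for the 48 less 24 h difference. Without a filter on low counts they were 79 (5 µM, 3 h), 3 and 1 (1 µM, 24 and 48 h), 25 (5 against 1 µM, 3 h) and 27 (48 less 24 h). With all libraries in 1 model they were 617 (5 µM, 24 h), 11 and 353 (5 against 1 µM, 3 and 24 h) and 38 (48 less 24 h). The Y-linked covariate gave 465 (5 µM, 24 h), 334 (5 against 1 µM, 24 h) and 32 (24 less 3 h). Without libraries of 1 sex they were 0 (1 µM, 24 h), 64 (5 µM, 24 h), 103 (5 against 1 µM, 24 h), 1247 (control 48 against 24 h), 16 (24 less 3 h) and 2 (48 less 24 h), and without the libraries high in haemoglobin 514, 553, 133 and 4 for the same 5 µM results except that of the control.

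With the replicate number as a block, counts were 62 for 5 µM at 3 h, 655 at 24 h, 2 for 1 µM at 24 h, 50 and 319 for 5 against 1 µM at 3 and 24 h, 28 for the 48 less 24 h difference, and 1618 for 5 against 1 µM at 48 h by library code number (1447 by title). The block changed no other count by over 1.5 times. Where numbers did not meet the rule for pairing, the block gave 30 higher and 32 lower for 5 µM at 3 h and called Sox9 there (edgeR adjusted p = 0.0319) and Col2a1 (0.0273) and Ihh (0.00681) for 5 µM at 48 h. In those comparisons the number of libraries of 5 that correlated best with their own number was 3 for 1 and 5 µM against control at 3 h, 4 for 5 µM at 48 h and 5 against 1 µM at 24 h, 2 for control 24 against 3 h and 48 against 24 h, and 1 for control 48 against 3 h. For 5 µM against control at 48 h the rule was narrowly missed, with a lowest correlation of 0.091 and a mean of 0.28, against -0.07 for other numbers. Library code numbers also paired each of these groups with 1 µM at 48 h. The blocked calls of Col2a1 and Ihh therefore cannot be set aside.

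Leaving out each library in turn gave 0 to 1, 15 to 45 (5 µM), 1 to 1, 109 to 498 (5 µM, 24 h), 0 to 0 and 912 to 1153 genes against control in order of time, 1 to 9, 95 to 553 and 718 to 948 for 5 against 1 µM, and 5582 to 6399, 2099 to 2675 and 7955 to 8425 for the control times. The differences of the 5 µM effect gave 30 to 109 and 2 to 17, and those of 1 µM 0 to 0.

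Some lists turned direction, with these camera adjusted p. Epidermis with 1 µM at 24 h turned without control 24 h replicate 3 (0.0262). Ribosomal proteins with 5 µM at 24 h turned with the Y-linked covariate (2.01e-05), without 5 µM 24 h replicate 5 (0.00251) and without high haemoglobin (0.0296), and against 1 µM without that replicate or the high-haemoglobin libraries (0.00102 each). Leaving out each library gave p of 0.0107 to 0.93 for that epidermis result, 0.00251 to 0.795 and 0.00102 to 0.855 for ribosomal proteins, 4.24e-06 to 0.885 for muscle with 1 µM at 48 h and 2.09e-05 to 0.797 for its 48 less 24 h difference, 1.13e-06 to 0.669 for glycolysis with 1 µM at 48 h, 0.00541 to 0.324 for glycolysis between doses at 24 h, and 1.63e-04 to 0.553 for oxidative phosphorylation in the 48 less 24 h difference. Without libraries of 1 sex, muscle with 1 µM at 48 h turned (0.979), as did its 48 less 24 h difference (0.837). Glycolysis turned with 1 µM at 48 h under the Y-linked covariate (0.431), without 1 µM 48 h replicate 2 (0.486) or libraries of 1 sex (0.015), and for 5 against 1 µM at 24 h without 5 µM 24 h replicate 4 (0.0241). Oxidative phosphorylation in the 5 µM 48 less 24 h difference turned without 5 µM 24 h replicate 5 (0.553) or high haemoglobin (0.925). The Y-linked covariate turned Y-linked genes by construction, in control 24 against 3 h Eif2s3y (-0.001), Uty (-0.063), Ddx3y (-0.23) and Kdm5d (-0.18), and in 48 against 3 h Uty (-0.10). Of the list calls an estimated correlation kept 16 and lost 197, while fry lost 112. Of the calls of named genes DESeq2 kept 839, limma-voom 828, all libraries in 1 model 814 and leaving out libraries of 1 sex 695, with 157 lost in the last.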

Other observations

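The tests of tubulin and of liver X receptor targets were written down before their members' values were seen but chosen after related genes had been. Tubb3 and Srebf1, counted as not seen before, also belong to fixed lists tested earlier, and Srebf1 had been called at 24 h. The test of genes that rise in culture was chosen only after the result was seen.

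Further genes changed with 5 µM BPAF at 48 h. The retinoic acid binding protein Crabp1 was higher by 0.36 ± 0.07 and the retinoic acid synthesis gene Aldh1a3 lower at -0.96 ± 0.19 (SE, n = 5 against 5). The small heat shock proteins of striated muscle, Hspb1 and Cryab, stood at -0.99 ± 0.12 and -0.95 ± 0.14. The keratocan gene Kera, a proteoglycan of tendon and cornea, fell by 0.99 ± 0.09 on the log2 scale, with Tppp3, a marker of tendon sheath, at -0.99 ± 0.13. Cyp1b1, a target of the aryl hydrocarbon receptor, rose by 0.78 ± 0.11, and Angptl4, a target of PPAR and of hypoxia, by 0.60 ± 0.08. The receptor Erbb3 of Schwann cells fell by 0.62 ± 0.09 and the patterning genes Hoxd10 and Hoxa11 were higher by 0.29 ± 0.07 and 0.27 ± 0.07.

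The libraries differed in the sexes of the pooled limbs. Y-linked genes were near absent (mean log2 CPM -2.94, -2.38 and -2.85) in control 3 h replicate 3, 1 µM 3 h replicate 1 and 1 µM 48 h replicate 2. Xist, the RNA of the inactive X chromosome, stood at 0.95 and 0.867 CPM in control 24 h replicates 2 and 3, 1.26 in 1 µM 24 h replicate 2 and 2.55 in control 48 h replicate 3, and between 349.5 and 2176 CPM in the other libraries.

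A first hypothesis was that tubulin mRNAs fall together at 5 µM and 3 h, after Tubb4b (-0.37 ± 0.05), Tuba1a (-0.41 ± 0.08) and Tubb5 (-0.31 ± 0.06) had been seen to fall. The other members were measured in the same libraries, and reads of near-identical tubulin copies may be divided between genes. Their fold changes are therefore not independent of those seen first. All 7 measured members not seen before had a fold change below 0, with a median of -0.33, and 6 were lower adjusted over the list alone but 0 over all genes by edgeR (fry p = 0.00105, camera p = 0.00591 with an estimated correlation). At 24 h their median was -0.33 with 4 called (limma fry adjusted p = 0.0266 over 12 tests, camera p = 0.081 with an estimated correlation), while the genes seen first were not called, with Tubb5 at 0.12 ± 0.07, Tubb4b at 0.06 ± 0.08 and Tuba1a at -0.03 ± 0.08. At 48 h the median was 0.00 with 3 lower and Tubb3, a neuronal tubulin, higher by 1.13 ± 0.20 (limma fry adjusted p = 0.842), and Tubb5 and Tubb4b were higher by 0.34 ± 0.07 (edgeR adjusted p = 0.0025) and 0.24 ± 0.07 (edgeR adjusted p = 0.035). With 1 µM at 3 h the median was -0.06 (limma fry adjusted p = 0.403). Tubulin mRNAs are degraded in response to free tubulin subunits, so a rise in free subunits may be one explanation, which was not measured.

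A second hypothesis was that targets of liver X receptors, nuclear receptors for oxysterols, fall together, after Abcg1 and Abca1 had been seen to fall. Another member, Apoc1, had been seen too and was left out of the test with them. It was lower at -2.60 ± 0.41 with 5 µM at 48 h (edgeR adjusted p = 4.57e-04) but not called at 24 h (-1.01 ± 0.43) or 3 h (0.27 ± 0.44), nor with 1 µM at 3 h (0.69 ± 0.45), 24 h (-1.06 ± 0.43) or 48 h (-1.22 ± 0.28). For the 8 members counted as not seen before the larger fry p of 24 and 48 h at 5 µM was 9.51e-04, with medians of -0.23 and -0.23. Of these 2 were called at 24 h and 3 at 48 h. Called at 48 h were Srebf1 at -0.62 ± 0.05, Mylip at -0.41 ± 0.07 and Apoe, an apolipoprotein also abundant in macrophages, at -0.98. Smpdl3a at -0.37, Lpcat3 at -0.08, Nr1h3 at -0.07, Arl4c at 0.01 and Pltp at 0.13 were not called at 48 h. Each member is given here whatever its result. At 1 µM the medians were -0.16 at 24 h (limma fry adjusted p = 0.00955) and -0.21 at 48 h (limma fry adjusted p = 0.00185), with 0 members called by edgeR over all genes and 2 and 3 lower adjusted over the list alone. At 3 h the limma fry adjusted p was 0.151 with 5 µM and 0.403 with 1 µM. Lower liver X receptor activity may explain this, and the lower macrophage genes beside it were not separated from it.

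The third hypothesis was that 5 µM BPAF lowers genes that rise in culture. Of 708 genes lower at 48 h and tested in both comparisons, 416 or 58.8% had risen between 3 and 24 h in control libraries, which do not enter the 48 h comparison, while the 2.5 and 97.5 percentiles of 10000 random sets matched on expression were 18.1 and 23.9%, and the highest was 26.4%. Without the muscle list the share was 57.5% of 680 genes, and without any listed gene 59.7% of 591. Muscle genes outside the lists were not taken out, so these shares do not separate the result from the fall of muscle genes. Among genes higher at 48 h the share was 33.3%, against percentiles of 20.3 and 28% in matched sets. A slowed course of all genes would also leave genes that fall in culture higher with 5 µM. For genes that fell between 3 and 24 h no such excess was seen. Of the 439 genes higher at 48 h 79 had fallen in that interval, where independent lists would share 81.6, while 146 had risen, where they would share 86.5. These expected numbers were not matched on expression. The chondrocyte and osteoblast lists, which rose in culture, were not called at 48 h. The count of genes that had fallen covers the interval from 3 to 24 h only, so it cannot decide on a delay after 24 h. A general delay of differentiation therefore stays open, as does why genes that rise in culture were lower.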
